A study of Arabidopsis thaliana with 9 samples.

How the data were processed

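The series holds 9 Affymetrix ATH1 arrays, one per sample, of RNA from whole Arabidopsis thaliana roots at 7 days after germination, with 3 arrays each of wild-type Col-0, the loss-of-function mutant scl3 (allele scl3-1, in Col-0) and a line overexpressing SCL3 (SCL3 OE, in Col-0). SCL3 is a GRAS-family regulator known to act in gibberellin signalling and in ground tissue of the root. Groups and replicate numbers came from the sample titles, and the series text calls the samples biological triplicates. The deposited values are linear signal intensities per probe set, made with MAS5 in Affymetrix Expression Console 1.1 per the submitters' processing notes. The deposited intensities of each array have a trimmed mean of 499.8, which is what scaling of each array to one target gives, and no detection calls were used here. Array medians ran from 158.5 to 191.1, less than 2-fold apart, so the values were used as deposited. The number of arrays limits the precision, and an array has no read depth.

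Values were analysed as log2(signal + 1), so that fold changes of dim probe sets are understated. The 64 control probe sets were left out of the tests. Of the 22746 plant probe sets, the 13647 with a mean log2 signal above the 40th percentile (6.65, a signal near 99.3) were tested. The annotation given with the series matrix named 13513 plant probe sets with 1 gene, 503 with several and left 8730 unnamed here, and many well-studied genes were among the unnamed. Of those with 1 gene, 13436 were matched by gene number to RefSeq's TAIR10.1 table for current symbols. A probe set with several genes was not named. For list tests, 1 probe set per gene was kept, the one with the highest mean signal, which gave 7325 genes.

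The fit was limma 3.58.1 in R 4.3.3, with group as the only term, all 9 arrays, an intensity trend in the variance prior, 2-sided moderated tests and Benjamini-Hochberg adjustment over the tested probe sets, with an adjusted p under 0.05 as the threshold. Probe sets were also counted with a change of at least 2-fold. The 3 comparisons were scl3 minus Col-0, SCL3 OE minus Col-0 and SCL3 OE minus scl3. Gene lists were tested with camera at its preset correlation of 0.01, with an estimated correlation and fry as alternatives. The variance trend was added to camera after a first run, and no call among the fixed lists changed. A single probe set was also tested with an exact 2-sided permutation test, whose smallest p is 0.1 for 3 against 3. The probe set of SCL3 itself was not named by the annotation used here, so the planned report of SCL3's transcript by name was not made. Figures were drawn with matplotlib 3.10.9.

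The design, the thresholds, the alternatives, 26 gene lists with 378 entries and the rule for named genes were fixed before the data were examined. The lists held 362 different genes, of which 63 had a named probe set and 48 were tested. Only 6 lists had at least 3 tested genes and were tested as lists. These were gibberellin signalling, DELLA targets and gibberellin response, the GRAS family, the cell cycle, cell wall and expansion, and auxin. No gene was tested from the lists of gibberellin metabolism, endodermis, root cap, cytokinin, brassinosteroid, ethylene, phosphate and nitrate. The lists of ground tissue regulators, cortex, root hair, iron and photosynthesis had 2 tested genes each, and those of stele, stem cell niche, abscisic acid, jasmonate and salicylate, touch, the clock and reference genes had 1. Named genes were, per comparison, the 8 with the highest and the 8 with the lowest log2 fold change among called probe sets of 1 gene whose groups did not overlap (or, with fewer than 5 called, the 5 with the smallest p), and up to 4 members per list that passed over all probe sets or over the list alone. From a list with none, the member with the smallest p could be given as a value that did not pass. For a list with 1 tested gene, the p over the list alone is the unadjusted p. Other genes named below are further members of the lists or were chosen after their values were seen.

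The 42 probe sets of spiked-in bacterial and phage control RNAs, which report on array handling and not on the plant, were clustered by complete linkage after the data were seen. Cut into 3, they gave array set 1 (Col-0 and scl3 replicates 1 and 2), array set 2 (Col-0 and scl3 replicate 3) and array set 3 (the 3 SCL3 OE arrays). Set 1 and set 2 each hold Col-0 and scl3, so the set was added as a fixed term that marks the set 2 arrays only, in fits chosen after seeing the data. Any offset of set 3 stays in the SCL3 OE differences of these fits. SCL3 OE lies alone in set 3, so genotype and array set cannot be told apart for it. A random block for the set and a fit without set 2 were also run. In the check for pairing by replicate number, deviations from the group mean correlated at 0.90, 0.89 and 0.95 between Col-0 and scl3 arrays of the same number. This pairing comes from the data and follows the array sets, since Col-0 and scl3 arrays of set 1 with different numbers also reached 0.89.

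The fits were tested on simulated data, with the spread and the set 2 difference estimated from these arrays and 200 of 13647 probe sets changed in each of 5 runs. The changes were spread about evenly over 1.5-fold, 2-fold and 4-fold. For scl3 minus Col-0, the fit with group only found 8.36% of 2-fold and 39.4% of 4-fold changes, and the fit with array set found 96.7% and 100%, with 7.61% of its calls false. For SCL3 OE minus Col-0, the values were 6.87% and 47.0% with group only, and 95.2% and 100% with array set. For SCL3 OE minus scl3, they were 8.36% and 52.1%, and 92.5% and 100%. The alternatives were no filter, a filter at the 60th percentile, quantile normalization, centring on the median, an offset of 32, variance priors without trend or robust, only the 6 arrays compared, array weights, a replicate block, and leaving out each array in turn. Genome coordinates were not used here.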

Results

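Whole-root RNA from 9 samples of Arabidopsis thaliana at 7 days after germination was measured on ATH1 arrays, with 3 arrays each of Col-0, the scl3 mutant and the SCL3 OE line. The design asks what the roots' transcripts do when SCL3 is lost and when it is overexpressed. The Col-0 arrays did not form one group, and neither did the scl3 arrays. In the control RNAs spiked into every sample, Col-0 and scl3 replicates 1 and 2 formed array set 1, Col-0 and scl3 replicate 3 formed set 2, and the 3 SCL3 OE arrays formed set 3. Over all plant probe sets, arrays of set 1 correlated at 0.959 to 0.962 with one another, the 2 arrays of set 2 at 0.943, and arrays of set 3 at 0.962 to 0.969. Set 2 correlated at 0.818 to 0.833 with the other arrays, and set 1 with set 3 at 0.932 to 0.944. These correlations are across probe sets, which are not independent replicates.

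Photosynthesis transcripts marked the arrays of set 2. RCA, the activase of Rubisco, had a mean log2 signal of 14.55 in set 2 (n = 2) against 8.14 ± 0.36 in set 1 (SD, n = 4) and 9.96 ± 0.19 in SCL3 OE (SD, n = 3). LHCB4.1, an antenna protein of photosystem II, stood at 14.25 in set 2, 8.00 ± 0.29 in set 1 and 9.34 ± 0.13 in SCL3 OE. Both genes are the tested members of the photosynthesis list fixed before the data were examined. Of 20 root-abundant genes, a list written after the data were seen, 17 were lower in set 2 (median -1.12), as were 5048 of all 7325 tested genes (median -0.42). PYK10, a beta-glucosidase abundant in roots, was at 14.05 in set 2 against 15.02 ± 0.10 in set 1, and EXPA7 and EXPA18, expansins of root hairs, had log2 differences of -1.45 and -1.99 in set 2 against set 1 (PYK10 was chosen after its values were seen). The 2 tested cortex genes were higher in set 2, AT1G09750 at 12.41 and 12.29 against 6.98 to 7.71 in set 1, and AT1G62500 at 10.41 and 9.96 against 6.87 to 7.52. In the limma fit with array set as a term, 10479 of 13647 probe sets differed between set 2 and set 1, of which 3009 were higher and 7470 lower in set 2. Col-0 and scl3 each hold 1 array of set 2, so this difference widens the spread within both groups and leaves the mean difference between them.

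**Figure D1:**
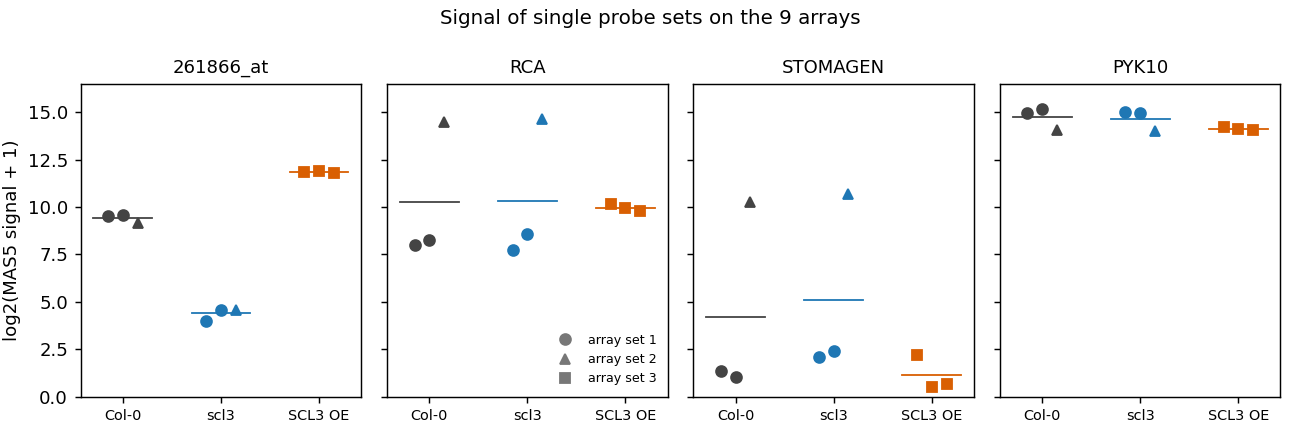
Log2(MAS5 signal + 1) of 4 probe sets on each of the 9 arrays, by genotype; each point is 1 array, its shape gives the array set, and lines are group means. Probe set P1, in the leftmost plot under its array ID, separates the 3 genotypes in every array, while RCA and STOMAGEN are high on the set 2 arrays of Col-0 and scl3 (RCA 14.55 against 8.14 in set 1) and PYK10 is lower there.

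Between scl3 and Col-0, 1 probe set was called in the fit with group only. This probe set, which the annotation used here does not name and which is called P1 below, had a log2 signal of 9.42 ± 0.25 in Col-0 and 4.39 ± 0.34 in scl3 (SD, n = 3), a log2 fold change of -5.03 ± 0.22 (SE) or 32.7-fold lower, and -3.78 with an offset of 32, since the scl3 signals lay far below the filter on mean signal. Its adjusted p was 0.00021 in limma. All 3 scl3 values lay below all 3 Col-0 values, and the exact permutation p was 0.1, the smallest that 3 against 3 can give. It was lower in scl3 within array set 1 (-5.28, 2 against 2) and within array set 2 (-4.54, 1 against 1). No other probe set passed in limma, and 50 of 13647 had an unadjusted p under 0.05. With array set as a term, again 1 probe set passed, with 1143 at an unadjusted p under 0.05. Unchanged probe sets would give a share of 0.05, and the 50 lie under that share and the 1143 above it. Changes that were not called stay open, since the fit with group only found 8.36% of simulated 2-fold and 39.4% of 4-fold changes.

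Among genes with a name, none passed between scl3 and Col-0. The 5 with the smallest p, none of them passing (adjusted p = 1 each in limma), were AT2G04620 (log2 fold change 0.94 ± 0.21, SE), AT2G18600 (0.81 ± 0.23), AT3G01400 (-0.42 ± 0.13), AT5G57785 (-0.41 ± 0.13) and AT1G71430 (0.43 ± 0.15). No fixed list with at least 3 tested genes was called by camera. Of the GRAS family, the family of SCL3, 7 of 8 tested members had negative fold changes, with a median of -0.13 and a camera adjusted p of 0.165 (limma; adjusted p = 0.383 with an estimated correlation). The DELLA target and gibberellin response list had 3 tested genes and a median of 0.22, with the same camera adjusted p of 0.165. Its member GID1B, a gibberellin receptor, had 0.36 ± 0.19 (SE) and did not pass (adjusted p = 0.272 over the list alone, limma). The other members, GID1A and XERICO, had 0.22 ± 0.75 and -0.01 ± 0.18. In gibberellin signalling, 3 of 7 members were positive and the median was -0.08 (camera adjusted p = 0.888, limma). Cell wall and expansion (9 genes, median -0.01), the cell cycle (3 genes, -0.03) and auxin (4 genes, 0.03) each had a camera adjusted p of 0.888 (limma), and the median and the test of auxin differed in sign, as did the mean and the test of cell wall and expansion. No member of these 6 lists passed, also when adjusted over the list alone. The touch list's single tested member STZ, a zinc finger repressor, had -0.51 ± 0.20 (SE), with an unadjusted p of 0.0373 and an adjusted p of 1 over all probe sets (limma). Without the arrays of set 2, the DELLA target list (positive) and cell wall and expansion (negative) passed camera at an adjusted p of 0.0443 each (limma), a fit in which no estimated correlation was run. Neither was called in the fit with array set (adjusted p = 0.126, and 0.816 with cell wall positive, limma) or there with an estimated correlation (0.569 and 0.834).

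In SCL3 OE, the 8 named genes with the largest rise against Col-0 were led by AT4G07820 and SWEET3, and the 8 with the largest fall by OCT1. AT4G07820 rose 7.68-fold (log2 fold change 2.94 ± 0.49, SE), and SWEET3, a member of a sugar transporter family, rose 7.22-fold (2.85 ± 0.47). AT5G05250 (2.16 ± 0.35), AT3G07720 (1.88 ± 0.20) and AT1G47400 (1.81 ± 0.31), all known to respond to iron deficiency, rose, as did AT2G40230 (1.91 ± 0.29), AT4G25250 (1.56 ± 0.26) and IVD (1.62 ± 0.18), isovaleryl-CoA dehydrogenase of leucine breakdown. Their adjusted p values in limma ran from 0.0107 to 0.0405. SWEET3 and AT1G47400 had low mean signals in Col-0 (69.5 and 63.2), and log2 fold changes of 2.294 and 1.425 with an offset of 32. The fall was led by OCT1, an organic cation transporter, with a mean signal of 1.16 in SCL3 OE against 1170 in Col-0. Its log2 fold change of -8.61 ± 0.79 (SE, adjusted p = 0.00822, limma) rests on a signal at the floor and is -4.73 with an offset of 32. ChiC, a chitinase, fell by 4.64 on the log2 scale (25-fold, SE 0.21, adjusted p = 0.000342, limma). AT2G43620 (-4.65 ± 0.49), AT2G04460 (-5.21 ± 0.77), AT3G47480 (-4.92 ± 0.85), AT5G39580 (-3.90 ± 0.51), AT2G39400 (-3.47 ± 0.53) and AT5G20790 (-3.17 ± 0.45) fell too, with limma adjusted p from 0.0107 to 0.0405. Of these, AT2G43620, AT2G04460 and AT3G47480 had mean signals of 22.2, 31 and 16 in SCL3 OE, near the floor, and log2 fold changes of -3.46, -3.97 and -3.19 with an offset of 32. Each of the 16 genes was higher, or lower, in all 3 SCL3 OE arrays than in all 3 Col-0 arrays, as the rule for naming asked.

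**Figure D2:**
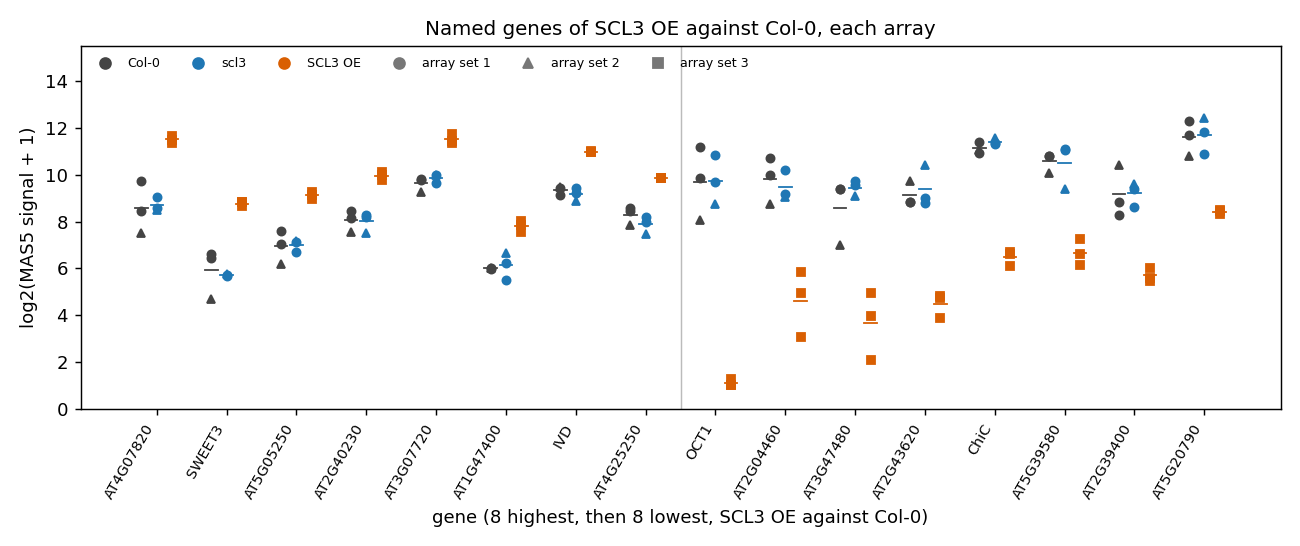
Log2(MAS5 signal + 1) of the 8 named genes that rose most and the 8 that fell most in SCL3 OE against Col-0; points are the single arrays of Col-0, scl3 and SCL3 OE, shapes give the array set and short lines the means of 3. The SCL3 OE arrays lie apart from all Col-0 arrays in each gene, OCT1 is at the floor in SCL3 OE (mean signal 1.16), and scl3 lies near Col-0.

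In all, 164 of 13647 probe sets passed between SCL3 OE and Col-0 in limma, 60 higher and 104 lower, and 135 of them changed at least 2-fold (44 higher, 91 lower). Probe set P1 rose from 9.42 ± 0.25 to 11.84 ± 0.06 (SD, n = 3), a log2 fold change of 2.42 ± 0.22 (SE, 5.34-fold, adjusted p = 0.00822 in limma, exact permutation p = 0.1). The count depended on single arrays. Without SCL3 OE replicate 1, 2 or 3 there were 5, 6 and 4 calls and without Col-0 replicate 1 there were 7, all lower, and P1 missed the threshold in these 4 (adjusted p 0.0511 to 0.0702, limma), although its log2 fold change stayed between 2.27 and 2.5 whichever array was left out. There were 38 without Col-0 replicate 2, 46 and 77 without scl3 replicate 1 and 2, 258 without Col-0 replicate 3 and 327 without scl3 replicate 3. The count also depended on how the array sets were treated. With array set as a fixed term 4590 probe sets passed (2403 higher, 2187 lower), and without set 2 there were 5182. All 164 were among them with the same sign in both fits. The fixed term marks set 2 only and takes no offset of set 3 out of the SCL3 OE differences. When the set was a random block, 0 passed in limma, with 250 at an unadjusted p under 0.05. Each SCL3 OE array lies in set 3 and no other array does, so genotype and array set cannot be told apart in this comparison and the next.

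Of the ground tissue regulators, 2 genes were tested, and neither passed over all probe sets in SCL3 OE with group only. JKD, a zinc finger partner of SHORT-ROOT and SCARECROW, had a log2 fold change of 0.93 ± 0.24 (SE, adjusted p = 0.124 over all probe sets and 0.0089 adjusted over the list alone, limma). SLY2, an F-box protein of gibberellin signalling that is also listed with the ground tissue regulators, had -1.43 ± 0.43 (SE, adjusted p = 0.189 over all probe sets and 0.011 adjusted over the ground tissue list alone, but 0.0767 over the gibberellin list alone, limma). In gibberellin signalling, 5 of 7 members were positive, 0 passed over all probe sets or adjusted over the list alone, and the median (0.14) and the mean (-0.08) differed in sign (camera adjusted p = 0.84, limma). The gibberellin receptor GID1A was at 9.15 ± 0.06 in SCL3 OE and 8.94 ± 1.36 in Col-0 (SD, n = 3). Once array set was a term, its log2 fold change was 0.94 ± 0.11 (SE, adjusted p = 8.01e-05, limma). STZ, the only tested member of the touch list, fell by 2.90 on the log2 scale (SE 0.20, adjusted p = 0.00276, limma). WRKY53, a transcription factor of senescence and defence, had -1.42 ± 0.52 (SE), with an adjusted p of 0.291 over all probe sets (limma). Its unadjusted p was 0.0271 (limma), which is also its p over its list of 1 tested gene. In the fit with array set, JKD (0.81 ± 0.19, adjusted p = 0.00709), SLY2 (-1.82 ± 0.18, 2.17e-05) and WRKY53 (-1.81 ± 0.32, 0.00124) each passed over all probe sets (SE, limma).

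Besides ground tissue, touch and the WRKY53 list, fixed lists with 1 or 2 tested genes had none that passed with group only in any of the 3 comparisons, adjusted over the list alone included. For a list of 1 tested gene that p is unadjusted. Adjusted over all probe sets with group only, WRKY53 did not pass, and STZ passed only in SCL3 OE. Against Col-0, the cortex genes AT1G09750 and AT1G62500 had log2 fold changes of -0.54 ± 1.7 and -2.05 ± 1.0 in SCL3 OE (SE), and the iron genes PYE and AT3G13610 had 0.12 ± 0.19 and -0.21 ± 0.43. The root hair expansins EXPA7 and EXPA18 had 0.98 ± 0.53 and 0.21 ± 0.69, LHW of the stele -0.09 ± 0.49, AGL42 of the stem cell niche 0.57 ± 0.80 and COR47 of the abscisic acid list 0.31 ± 0.42. GI of the clock (0.20 ± 0.20) and the reference gene AT4G34270 (0.32 ± 0.30) moved little. RCA and LHCB4.1 had -0.28 ± 2.2 and -0.69 ± 2.1. The fit with array set called RCA (1.85, adjusted p = 3.33e-05), LHCB4.1 (1.39, 6.68e-05), AT1G09750 (1.14, 0.00123), AT1G62500 (-1.07, 0.000983), AT3G13610 (-0.62, 0.000986), LHW (-0.56, 0.00222) and EXPA7 (0.49, 0.0464) over all probe sets (limma). Signs turned between the fits for RCA, LHCB4.1, AT1G09750, EXPA18 (-0.45), AGL42 (-0.20) and COR47 (-0.07), the last 3 without a call.

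Of the 9 tested genes of cell wall and expansion, 6 had negative fold changes in SCL3 OE and the median was -0.48. The list was not called (camera adjusted p = 0.0942, limma, and adjusted p = 0.737 with an estimated correlation). None passed over all probe sets and 3 did adjusted over the list alone, each at an adjusted p of 0.0364 (limma). These were XTH26, a xyloglucan endotransglucosylase (-1.88 ± 0.58, SE), the expansin EXPA8 (-1.06 ± 0.27) and the expansin EXPB1, which lay the other way (1.96 ± 0.60). Adding array set as a term, 7 of the 9 fell and 1 rose over all probe sets, all 9 passed adjusted over the list alone, and camera called the list (adjusted p = 0.0188, limma, and adjusted p = 0.545 with an estimated correlation). The same genes were lower in set 2 than in set 1, with a median of -1.34. The GRAS family (8 genes, median -0.09, camera adjusted p = 0.582), the DELLA target list (3 genes, median 0.21, 0.582), the cell cycle (3 genes, median 0.19, 0.912) and auxin (4 genes, median 0.56, 0.84) had no member that passed in limma with group only, and the median and the test of the cell cycle differed in sign. The fit with array set called GID1A and XERICO (0.55, adjusted p = 0.0118) of the DELLA targets, AT5G66770 (0.66, 0.0136) and AT1G63100 (-0.84, 0.0228) of the GRAS family, AUR2 (-0.56, 0.0181) of the cell cycle and GH3.3 (1.75, 0.000893) of auxin (limma).

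**Figure D3:**
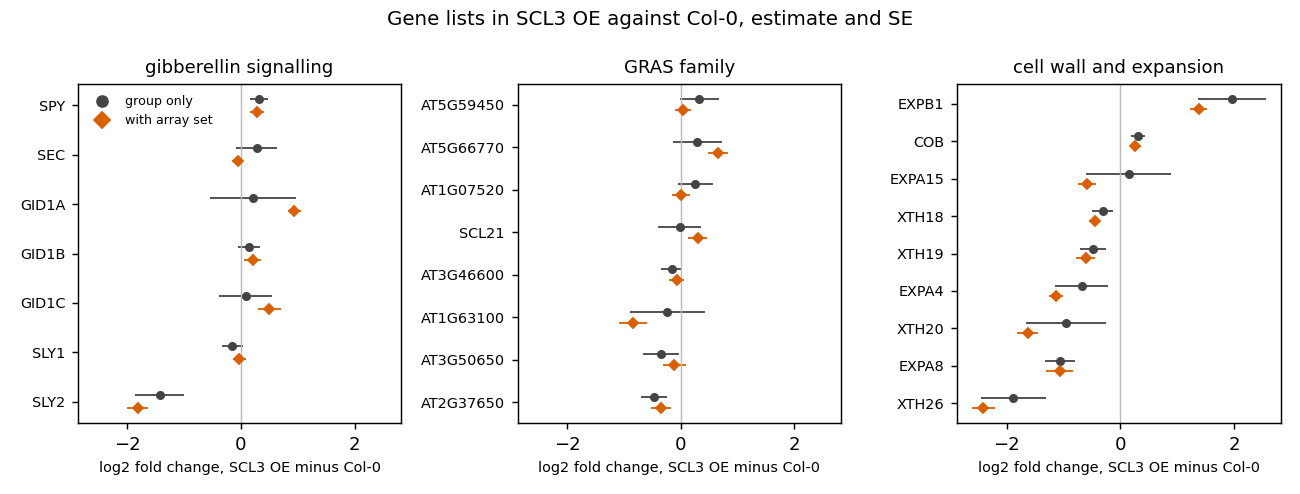
Log2 fold change of SCL3 OE minus Col-0, with its SE, for the tested genes of 3 fixed lists; circles are the fit with group only and diamonds the fit with array set as a term. In cell wall and expansion XTH26 lies lowest (-1.88) and EXPB1 highest (1.96) in both fits, and the errors with group only are wider where the set 2 arrays differ from the rest, as in GID1A (0.75 against 0.11).

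SCL3 OE against scl3 gave 260 probe sets in limma, 129 higher and 131 lower, of which 192 changed at least 2-fold (84 higher, 108 lower). Of the 164 probe sets called against Col-0, 151 were also called here, all with the same sign. The highest named genes were SWEET3 (log2 fold change 3.05 ± 0.47, SE), AT3G45700 (2.80 ± 0.43), AT4G07820 (2.79 ± 0.49), XTH21, a xyloglucan endotransglucosylase (2.57 ± 0.38), AT1G31710 (2.33 ± 0.32), AT1G72200 (2.28 ± 0.42), TINY, an AP2-type transcription factor listed as tny (2.24 ± 0.41), and AT5G05250 (2.12 ± 0.35). The lowest were OCT1 (-8.64 ± 0.79, and -4.76 with an offset of 32), AT3G47480 (-5.79 ± 0.85), AT2G43620 (-4.92 ± 0.49), ChiC (-4.92 ± 0.21), AT2G04460 (-4.87 ± 0.77), AT5G39580 (-3.83 ± 0.51), AT2G39400 (-3.50 ± 0.53) and AT5G45670 (-3.37 ± 0.36). With an offset of 32, AT3G47480, AT2G43620 and AT2G04460 had -3.97, -3.72 and -3.64. SWEET3, XTH21 and AT1G31710, with low mean signals in scl3 (51.6, 64.6 and 61.9), had 2.484, 2.059 and 1.858 with that offset. The limma adjusted p of the named highest and lowest genes ran from 0.000109 to 0.0409. Probe set P1 was 7.45 ± 0.22 (SE) higher in log2 signal, or 175-fold, and 6.15 higher with an offset of 32 (adjusted p = 9.67e-06, limma, exact permutation p = 0.1).

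Against scl3, JKD had 1.07 ± 0.24 and SLY2 -1.53 ± 0.43 (SE), with adjusted p of 0.00419 and 0.00773 adjusted over the list alone for ground tissue (limma). SLY2 had 0.0541 over the gibberellin list alone, and neither passed over all probe sets with group only, while both did in the fit with array set (0.94, adjusted p = 0.00252, and -1.92, 1.13e-05, limma). STZ fell by 2.40 on the log2 scale (SE 0.20, adjusted p = 0.00591, limma). WRKY53 (-0.92 ± 0.52, SE) had an unadjusted p of 0.117 (limma) and did not pass with group only, but passed over all probe sets in the fit with array set (-1.31, adjusted p = 0.00731, limma). In cell wall and expansion, XTH26 (-1.98 ± 0.58), EXPA8 (-0.82 ± 0.27) and EXPB1 (1.96 ± 0.60) had an adjusted p of 0.0487 adjusted over the list alone (limma), and the list was not called (7 of 9 negative, median -0.45, camera adjusted p = 0.176). With group only, the other 5 lists had camera adjusted p of 0.991 each and no member that passed, adjusted over the list alone included, although the test and the median or mean differed in sign for gibberellin signalling, the GRAS family (medians 0.08 each) and the DELLA target list (-0.01), and fry gave an adjusted p of 0.0302 for auxin, in which all 4 members were positive (median 0.41). Besides SLY2, the fit with array set called members of these lists over all probe sets (limma). In gibberellin signalling these were GID1A (0.72, adjusted p = 0.000409), GID1C (0.86, 0.00557) and SPY (0.46, 0.0148), and XERICO (0.56, 0.00911) joined GID1A among DELLA targets. In the GRAS family these were AT5G66770 (0.76, 0.00592), SCL21 (0.48, 0.0396) and AT1G63100 (-0.79, 0.026). In auxin 1 gene was higher, and in the cell cycle 0 were called. With array set as a fixed term 5319 probe sets passed in limma, without set 2 there were 5521, and with the set as a random block there was 1, with 302 at an unadjusted p under 0.05. Leaving out 1 array gave 15, 10 and 8 without SCL3 OE replicate 1, 2 and 3, 8 and 63 without scl3 replicate 1 and 2, 148 and 149 without Col-0 replicate 1 and 2, and 658 without Col-0 replicate 3.

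Loss and gain of SCL3 were compared through their shared Col-0 arrays. Probe set P1 was the only one called in both comparisons against Col-0, and its signs were opposite. That count was 0 without Col-0 replicate 1 or any 1 SCL3 OE array. No probe set was called in both with the same sign. Independent lists of these sizes would share 0.0044 with opposite signs and 0.00762 with the same sign. Across the 13647 probe sets the log2 fold changes of scl3 and SCL3 OE had a Pearson r of -0.00333 and a covariance of -0.00042. Leaving out 1 array moved this r from -0.356 (without scl3 replicate 2) to 0.525 (without Col-0 replicate 2), so its sign rests on single arrays. Unchanged groups sharing the Col-0 arrays, simulated with the set 2 difference kept, gave an r of 0.155 (0.120 to 0.194 over 1000 simulations) and a covariance of 0.0112. With array set as a term, r was -0.0801 and the covariance -0.0095, against simulated values of 0.471 and 0.0112. The simulated groups were unchanged, while SCL3 OE had 4590 called probe sets against Col-0 in this fit. Such changes pull r toward 0 if they are unrelated to those of scl3, but then leave the expected covariance as it is. The covariance with array set lay below all simulated values (0.0103 to 0.0125). The simulations gave every array equal noise, independent between probe sets, which the real arrays need not follow. The gaps therefore do not settle whether the responses are opposite. With 3 Col-0 arrays the controls could not be split into parts of at least 2, and SCL3 OE's own array set is part of every value here.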

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

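Except for the test of shoot identity genes, all tests in this part were chosen after the results were seen. The poly-A control RNAs, added to each sample before labelling gave a median signal of 126 in the lowest SCL3 OE array, above the highest Col-0 array (96.9). They were among the controls that defined the array sets, so this difference is part of that grouping and no further evidence for it. Arrays of set 1 lay between 28.7 and 48.3, those of set 2 between 96.9 and 98.4. The hybridisation controls, added later, had median signals of 3460 to 4550 in set 1, 521 to 576 in set 2 and 778 to 890 in set 3.

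The first pattern is the distance of the Col-0 and scl3 replicate 3 arrays from the rest. Array processing alone is argued against by the photosynthesis genes. All 18 tested nuclear photosynthesis genes, a list written after the pattern was seen and holding some genes noticed first, were higher in set 2 (median 6.67 in log2), and the median lay at percentile 100 of 10000 random lists matched on mean signal. Greening of the roots alone is argued against by the 6 shoot identity genes given below, all higher in set 2. Of 20 root-abundant genes 17 were lower in set 2 (median -1.12 against -0.42 over all tested genes), at percentile 0.01. That list was written after the data were seen, and random lists take no account of genes that move together, so it decides nothing alone. The 2 tested cortex genes, AT1G09750 and AT1G62500, were higher in set 2. A share of green shoot tissue in the RNA may be the source. Its test, written before the values were seen, took leaf, stomatal and shoot meristem genes outside photosynthesis, of which 6 of 42 had a named probe set, and all 6 were higher in set 2 (median 4.66, percentile 100), STOMAGEN from 1.73 to 10.49, YAB5 from 3.33 to 8.95 and SPCH from 1.95 to 6.59 in mean log2 signal. None of the 6 passed the filter on mean signal, and the labels call all samples whole root.

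The second pattern is the difference of SCL3 OE from the other genotypes. Array set 3 holds all SCL3 OE arrays and no other, so handling of these arrays cannot be told apart from the genotype. Their maximum signals were 24105.6 to 28468.4, against 37734 to 59917.4 on the other arrays. The 3' to 5' signal ratio of ubiquitin was 1.05 to 1.2 in SCL3 OE and 1.26 to 1.52 elsewhere, while the ratios of actin and GAPDH overlapped. The set as a random block left 0 probe sets against Col-0 in limma (250 at an unadjusted p under 0.05) and 1, P1 (7.46, adjusted p = 0.0285), against scl3, but in this design the block widens the error of both contrasts in any case and decides nothing. Green tissue as in set 2 was tested by setting SCL3 OE minus Col-0 replicate 1 against Col-0 replicate 3 minus Col-0 replicate 2 across 13647 probe sets. The r of 0.283 lies between what a common cause and its absence were set to give. The nuclear photosynthesis genes lay 1.35 above set 1 in SCL3 OE in median log2 signal, as green tissue would need. The 45 plastid-encoded genes, 2.90 higher in set 2, lay the other way (-0.55, 9 of 45 higher). The 6 shoot identity genes were mixed in mean log2 signal. STOMAGEN (1.14 against 1.73 in set 1) and FMA (3.64 against 3.7) were lower in SCL3 OE. YAB3 (4.11 against 3.67), MUTE (1.82 against 1.31), SPCH (2.12 against 1.95) and YAB5 (3.36 against 3.33) were higher. These 6 genes lie near the floor in both sets and the plastid genes have a high baseline that would hide a small share, so a small share stays open. Of the 164 called probe sets, 46.3% had the same sign in both, but they were called with set 2 in the Col-0 spread. With 10 splits of the 6 arrays no share under 0.05 can be had: the real split alone (1 of 10) gave 164 probe sets against Col-0 and 260 against scl3 (1 of 10), and the highest of the other splits gave 0 in both comparisons. The genotype named by the labels stays among the open explanations.

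The third pattern is the single probe set called between scl3 and Col-0. Spread added by the replicate 3 arrays, as the reason for so few calls, was tested with array set as a term, which again called 1 probe set. Without the arrays of set 2 the count was also 1. The fit with array set found 96.7% of simulated 2-fold changes, with equal noise on every array. In each run 200 of 13647 probe sets changed, about evenly by 1.5-fold, 2-fold and 4-fold. The real arrays differed, as scl3 minus Col-0 had an SD over probe sets of 0.433 within set 2 (1 against 1) and 0.192 within set 1 (2 against 2). The single call argues against some 200 changes of such mixed sizes hidden by the set 2 shift, and fewer changes stay open. AT2G04620 (0.94 ± 0.18, SE), for one, had an adjusted p of 0.218 in that fit (limma). Smaller changes stay open too, since 69.3% of simulated 1.5-fold changes were found. For this comparison too, 10 splits are too few for a share under 0.05. The real split gave 1 and the highest of the others 0, which includes the 3 others that part all 3 same-numbered pairs.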

How the results depend on the processing

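The count between scl3 and Col-0 was 1 in every alternative run, and probe set P1 kept its sign in all 3 comparisons in all of them. Its adjusted p for scl3 minus Col-0 stayed under 0.05, while its rise in SCL3 OE over Col-0 kept its size but missed the threshold with array set as a random block (2.43, adjusted p of 1 in limma) and without Col-0 replicate 1 or any 1 SCL3 OE array (adjusted p 0.0511 to 0.0702). Counts of SCL3 OE against Col-0 (164, and 135 at 2-fold) moved to 264 with each array centred on its median, to 81 and 78 with only the 6 arrays compared, and to 5654 and 937 with array weights, which gave Col-0 and scl3 replicate 3 weights of 0.046 and 0.051. Chosen after seeing the data, array set as a fixed term gave 4590 and 903, array sets 1 and 3 only 5182 and 958, and the random block 0 and 0. Against scl3 (260 and 192), array weights gave 6073 and 1035, the fixed term 5319 and 1051, sets 1 and 3 only 5521 and 1024, and the random block 1 and 1. Fewer arrays or a smaller residual spread enter by construction, and the cause was not otherwise tested. Centring moved the share of higher calls from 36.6% to 29.2% against Col-0 and from 49.6% to 35.3% against scl3, since the median of all tested probe sets shifted from 0.131 to 0.012 and from 0.123 to 0.003 in log2. With no filter that share was 26.9% against Col-0 and 40.3% against scl3, and with a filter at the 60th percentile it was 48.7% and 59%.

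Leaving out 1 array gave 4 to 327 probe sets against Col-0 (4 to 233 at 2-fold) and 8 to 658 against scl3 (8 to 373), and 1 to 1 for scl3 minus Col-0. The lowest counts came without SCL3 OE replicate 3 (4 and 8) and without scl3 replicate 1 (8 against scl3), and without Col-0 replicate 1 there were 7 against Col-0. The highest came without scl3 replicate 3 (327) and without Col-0 replicate 3 (658). The log2 fold change of P1 ran from -5.18 to -4.83 in scl3, from 2.27 to 2.5 in SCL3 OE against Col-0 and from 7.25 to 7.55 against scl3. The r of both lines ran from -0.36 to 0.53, and the count with opposite signs from 0 to 1 (0 also with the random block). List calls ran from 0 to 2 in scl3 minus Col-0 (2 without Col-0 replicate 3), 0 to 1 in SCL3 OE minus Col-0 and 0 to 0 against scl3. In scl3 minus Col-0, camera called DELLA targets (positive) and cell wall (negative) without Col-0 replicate 3 (adjusted p = 0.0141 each). It called the GRAS family (negative) without Col-0 replicate 2 (0.0201) and DELLA targets (positive) without scl3 replicate 1 (0.0336).

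Of the 6 fixed lists, 0 were called in each comparison. Added after seeing the data, array sets 1 and 3 only, and set 1 only, gave 2 in scl3 minus Col-0 (DELLA targets and cell wall). In SCL3 OE minus Col-0, array weights, the fixed term and sets 1 and 3 only each gave 1 (cell wall). Against scl3, the fixed term and sets 1 and 3 only gave 1 (cell wall) and fry with group only gave 1 (auxin). With the fixed term, fry lost auxin (adjusted p 0.117) and called DELLA targets and cell wall, both against scl3 (0.0059 and 0.00898) and against Col-0 (0.000866 and 0.011). No fixed list was called with an estimated correlation, which was run with group only and with the fixed term. camera takes no robust prior and no random block, so these were not run for lists. The replicate number as a block gave 1, 205 and 369 probe sets. SCL3 OE shares only a number with the other groups, as its same-numbered arrays correlated at -0.10, 0.07 and -0.09 with Col-0, and not every array correlated best with its own number. The replicate block changed no list or P1 call. Over 1099 alternatives for named genes, 0 changed sign, 217 lost and 39 gained a call. These genes were picked for a small p or a large fold change, which makes a change of sign unlikely. RCA, LHCB4.1, AT1G09750, EXPA18, AGL42 and COR47 lie outside this count, and their signs turned in SCL3 OE minus Col-0 with array set as a term. The planned result for SCL3's transcript by name was not run. Signals near the floor, as in OCT1, limit how large a fall can be read.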

Other observations

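The lists and tests in this part were chosen after the data were seen. Genes known to respond to elicitors and wounding lay lower in SCL3 OE than in Col-0. Of 17 tested genes in such a list, 15 had negative fold changes, 7 fell and 0 rose over all probe sets, and the median was -1.66 (camera adjusted p = 1.05e-17 over the lists added later, limma, and adjusted p = 0.000473 with an estimated correlation). STZ (-2.90), AT4G27280 (-2.07 ± 0.31, SE) and AT2G22880 (-1.88 ± 0.26) were among them. Of 8 iron deficiency genes, 7 had positive fold changes and 3 rose, with a median of 1.63 (camera adjusted p = 8.5e-05, limma, and adjusted p = 0.179 with an estimated correlation). All 4 tested phosphate starvation genes had negative values and 3 fell (median -2.75, camera adjusted p = 8.2e-09, limma, and adjusted p = 0.0123 with an estimated correlation, which became 0.164 once array set was a term). These 3 lists hold genes first seen among the calls, so their tests are not independent evidence. The iron list fixed before the data were examined had 2 tested genes, PYE (0.12) and AT3G13610 (-0.21), and neither rose. AT3G13610 was lower once array set was a term (-0.62, adjusted p = 0.000986, limma).

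Nuclear photosynthesis genes and genes of the plastid genome moved apart in SCL3 OE once array set was a term. The plastid list takes all tested genes of that genome and is not limited to photosynthesis. Of 18 nuclear genes 16 rose (median 1.22, camera adjusted p = 5.75e-11, limma, and adjusted p = 0.109 with an estimated correlation), while of 45 plastid-encoded genes 24 fell and 3 rose (median -0.54, camera adjusted p = 3.57e-06, limma, and adjusted p = 0.187 with an estimated correlation). With group only, both medians were negative (-0.87 and -1.49), because the Col-0 mean then holds the set 2 array, so the direction of the nuclear genes turns with this choice. The root-abundant list had a median of -0.10 in that fit (20 genes, 4 higher and 6 lower, camera adjusted p = 0.163, limma).

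Large falls outnumbered large rises in SCL3 OE. In the fit with array set, 57 probe sets were at least 8-fold lower than in Col-0 and 7 at least 8-fold higher in limma. Against scl3, 64 were at least 8-fold lower and 9 at least 8-fold higher. The filter on mean signal favours falls in SCL3 OE, which has 3 of the 9 arrays, and without it the counts were 129 lower and 18 higher against Col-0 and 155 lower and 24 higher against scl3.

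Whether the added lists moved beyond the genes that led to them was tested on the members that were not called against Col-0. A hypothesis is that iron deficiency genes rise as a group in SCL3 OE: of 5 such members, 3 had all SCL3 OE values above both Col-0 values of set 1, with a median log2 fold change of 0.61 with array set as a term. A second hypothesis is that elicitor and wound genes fall as a group: of 10 such members, 7 had all SCL3 OE values below both Col-0 values of set 1, with a median of -1.53. Of all 7249 genes not called, 30.3% lay wholly above and 27.9% wholly below in the same way. Both lists were written after the calls were seen, so these counts decide neither hypothesis, and either difference may come from array set 3 as well as from the genotype. In scl3 minus Col-0, 13 of the 17 elicitor genes were negative (median -0.11), and camera with an estimated correlation gave p = 0.0161 with array set as a term (adjusted p = 0.0968 over the added lists, limma, which does not pass, against 0.0291 with group only). The list was written from genes low against the same 3 Col-0 arrays, so chance values of Col-0 would lower it here too, and no effect of scl3 can be read from it.

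Probe set P1 may measure the SCL3 transcript. P1 was called lower in scl3 and higher in SCL3 OE than in Col-0, the directions that a loss-of-function allele and an overexpression line would give. Only 1 probe set was called in scl3 at all, so its being the only such probe set adds nothing. Leaving out 1 array kept the log2 fold change of P1 between 2.27 and 2.5 in SCL3 OE. P1 missed the threshold there without Col-0 replicate 1 or any 1 SCL3 OE array. The annotation used here does not name it, so this stays a hypothesis, and the labels were not checked by the targeted gene's name.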
